A study of Mus musculus with 12 samples.

How the data were processed

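Messenger RNA levels were measured in embryos of ICR mice on 12 Affymetrix Mouse Genome 430 2.0 arrays, 2 for each of 6 groups. Labelled RNA was made from 0.1 µg of total RNA with 2 rounds of amplification, per the labels' protocols. The series' design text names GCOS 1.2 and GeneSpring 7.3 as the authors' software, and the submitters' processing notes name GCRMA, which corrects the background, quantile-normalizes the arrays and summarizes the probes of a set. The deposited values were linear intensity values per probe set, on the scale GCRMA gives after its logarithm has been undone. Any further step in GeneSpring is not given in the sources used here, so their absolute unit is arbitrary. The median intensity per array lay between 10.8 and 11.5 and the highest value between 39856 and 49391.

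Of the 45101 probe sets, 64 were Affymetrix controls. The annotation table paired 34958 probe sets with 1 gene symbol, 932 with several and 9211 with no symbol. Of the named probe sets, 34754 had an Entrez ID in the RefSeq gene table of assembly GRCm38.p6, which was used for names only, and 0 symbols needed an update. Each of the 18194 named genes was represented by the probe set with the highest mean level over all arrays. Values were taken as log2(intensity + 1), so every log2 difference refers to that scale, and no further normalization was applied. Genes with a log2 level of at least 5 on at least 2 arrays were tested, which left 9930. Of 360 calls of named genes between groups, 136 had a group under this level on both arrays and 3 had both groups under it. The size of such a difference rests on signal near background, and for some it is also given as at least the distance to a level of 5. Statements of the largest changes follow the fitted differences. Unnamed probe sets and those with several symbols were fitted separately and named nowhere.

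All 12 arrays entered 1 linear model in limma 3.58.1 (lmFit, contrasts.fit and eBayes; R 4.3.3) with a mean for each group and no other term. Pooling the groups gave 6 residual degrees of freedom, to which eBayes added 4.51 from the prior. The contrasts were 9 differences between groups and 1 interaction, the step from released day 3.5 to released day 4.5 minus the step from control day 2.5 to control day 3.5. Genes with a Benjamini-Hochberg adjusted p from limma's moderated test under 0.05 were called changed. All adjusted p-values for genes come from this fit unless stated, and errors of differences are standard errors. The contrasts, the named lists, the rule for naming genes and the alternatives were fixed before the data were examined. The sources used here name no test of the study.

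The 22 gene lists were ERK target genes, ERK cascade components, 2-cell stage genes, maternal oocyte genes, trophectoderm markers, inner cell mass and pluripotency genes, primitive endoderm markers, junction and blastocoel genes, S phase and DNA replication genes, mitosis genes, p53 targets and cell cycle inhibitors, stress response genes, ribosome biogenesis genes, ribosomal protein genes, oxidative phosphorylation genes, glycolysis genes, cholesterol synthesis genes, DNA methylation and chromatin regulators, and markers of cumulus and granulosa cells, oviduct epithelium, sperm, and blood and immune cells. They held 583 entries and 580 different genes, of which 517 entries matched the array. Lists with at least 5 tested genes were compared with all other genes by camera, which is competitive, with a preset correlation between genes of 0.01 and with a correlation estimated for each list. The adjustment covered the lists within a comparison. The 4 lists of other cell types had fewer tested genes and were not tested as lists.

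For the set tests listed next, developmental sets were chosen on arrays that the tested contrast did not use. A later look at the rising genes in released against control day 3.5 embryos shared the control day 3.5 arrays with the choice. Genes higher or lower in control day 3.5 than in control day 1.5 embryos were tested at day 2.5 under U0126 and in released day 3.5 embryos, each against control day 2.5. Genes that rose or fell from control day 1.5 to control day 2.5 were tested in released day 4.5 against control day 3.5 embryos. A position per array was the mean level of the rising minus that of the falling genes, scaled to 0 for the mean of control day 1.5 and 1 for that of control day 3.5. The position is described without a test. An exact 2-sided test of 2 arrays against 2 cannot go below p = 0.333, and a test with the spread pooled over the groups was not made.

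Genes were named by a rule with 3 parts. In 5 comparisons (U0126 day 2.5 and released day 3.5 against control day 2.5, released day 4.5 against control day 3.5, and the 2 control steps) part a took the 8 largest rises and the 8 largest falls among genes that passed with no overlap between the arrays of both groups. In the other comparisons it took 4 of each. It skipped probe sets with no or several symbols and RIKEN or predicted genes without a name. Part b took, in those 5 comparisons, up to 3 members of each list that passed, with the largest changes, or up to 2 with the smallest p where none passed. Part c took Dusp6, Spry4, Egr1, Fos, Etv4, Etv5, Myc, Ccnd1, Cdkn1a, Pou5f1, Nanog, Cdx2, Gata6, Sox17, Zscan4c and Zp3 wherever measured. The text gives a choice of these genes, made after their values were seen, with a few list members and genes outside the range of both controls beyond them.

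The groups shared replicate numbers 1 and 2. The differences between replicate 2 and replicate 1 correlated across genes in all 15 pairs of groups (r from 0.125 to 0.417), and on the fourth principal component, with 3.77% of the variance, replicate 2 lay above replicate 1 within each of the 6 groups, although the numbers overlapped across groups. The numbers were therefore treated as pairing the arrays, on the evidence of the data and of a series text that speaks of 2 experiments. The fit nevertheless had no block, as designed, so its counts ignore the pairing; for U0126 day 2.5 against control day 2.5 it gave 1384 genes and the block 2061. A fit with the number as a block, with 5 residual degrees of freedom, is given where it changed a call or moved a count by over 1.5 times. The other alternatives were leaving out each array in turn, with the array left alone in its group assumed to vary like the other groups, quantile normalization, median centring, no filter, a minimum log2 level of 7, a pseudocount of 16, a mean-variance trend, the mean of all probe sets of a gene, the other probe sets of a named gene, only the arrays compared, and an added minimum of a 2-fold change.

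The fit was tested on simulated data for the comparison of U0126 day 2.5 with control day 2.5, with 9930 genes. It recovered 8 of 67 genes changed 2-fold (11.9%), 44 of 67 changed 4-fold (65.7%) and 58 of 66 changed 8-fold (87.9%), with 10 false calls among 9710 unchanged genes. A list of 20 genes shifted by 1 log2 unit was called, and 0 of 50 unchanged lists were. The simulated genes varied independently of each other, so this gives no rate of false calls for lists whose genes vary together. Far fewer genes were changed there than the 1384 called in the data, and the Benjamini-Hochberg cut-off depends on that share. Signal near background and a difference shared by replicate numbers were not simulated either. The recovery rates may therefore not hold for the data. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9 prepared the table and drew the plots.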

Results

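Gene expression was compared between mouse embryos that developed undisturbed, embryos held at the 4-cell stage by 20 µM U0126, an inhibitor of the kinases that activate ERK, and embryos that resumed division after the arrest. Controls came from day 1.5 (2 cells), day 2.5 (4 to 8 cells) and day 3.5 (morula to blastocyst). Treated embryos came from day 2.5 and released embryos from day 3.5 (given as 8 cells) and day 4.5 (morula to blastocyst), with 2 arrays per group. The arrays of a group correlated with r from 0.955 to 0.980 over 9930 genes, against a lowest r of 0.516 between any arrays, and the first principal component held 62.6% of the variance. The number of arrays limits the precision, with a median standard error of 0.35 log2 units for a difference between groups. The series text speaks of 2 independent experiments, but the labels do not say that the replicates were separate cultures or animals. The p-values therefore measure the spread between these samples, which may be technical.

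The place of each group along normal development was read from 3485 genes that were higher and 2869 that were lower in control day 3.5 than in control day 1.5 embryos. On a scale from 0 at day 1.5 to 1 at day 3.5, control day 2.5 lay at 0.774 ± 0.0170 (SD, n = 2) and U0126-treated embryos of the same day at 0.608 ± 0.0414. Further on lay released day 3.5 embryos at 0.932 ± 0.00283 and released day 4.5 embryos at 1.02 ± 0.00530. The arrays of treated embryos, at 0.637 and 0.578, both lay below those of control day 2.5, at 0.786 and 0.762. The control arrays that set the ends of the scale also chose its genes, and change in other genes is not measured by it. A position near 1 therefore does not mean a profile like control day 3.5. On the second principal component (18.7% of the variance) released day 4.5 arrays lay at 57.3 and 61.0, control day 3.5 arrays at 22.4 and 0.56.

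**Figure D1:**
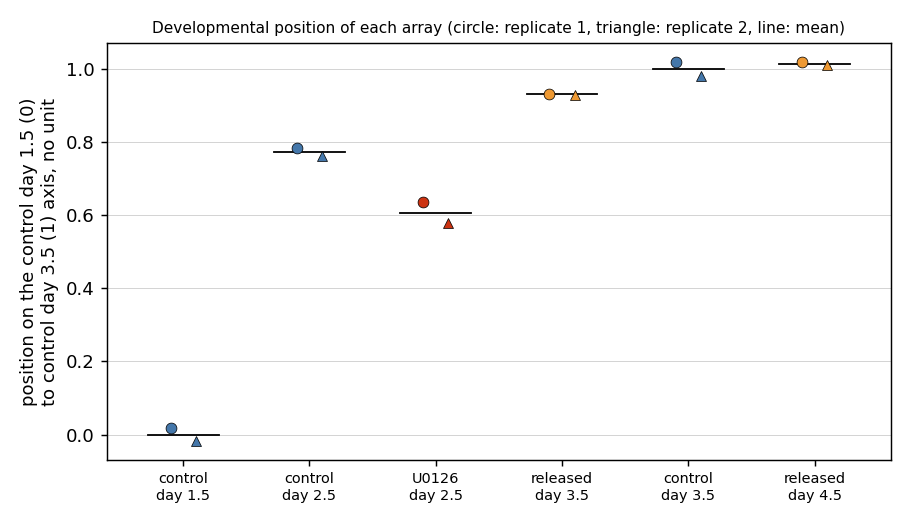
Position of each array on the axis from control day 1.5 (0) to control day 3.5 (1), in units of that distance. The line marks the mean of a group, which was 0.608 in U0126-treated embryos and 1.02 in released day 4.5 embryos.

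The step from 2 cells to 4 to 8 cells gives the background of normal development. Transcripts stored in the oocyte collapsed, among them Tcl1 (-7.95 ± 0.26 log2, adjusted p = 7.33e-08, n = 2 per group), a cofactor of Akt kinases. Also lower were Wee2 (-8.70 ± 0.70, adjusted p = 3.22e-06), which holds the oocyte in meiosis, and Pkd2l2 (-8.87 ± 0.37, adjusted p = 1.11e-07). Vnn1, a pantetheinase, rose most (9.04 ± 0.51, adjusted p = 3.98e-07), from 4.21 ± 1.39 to 13.26 ± 0.16 (mean ± SD). Genes of the later lineages came on, with Cdx2 (4.57 ± 0.35, adjusted p = 2.51e-06) and Krt8 (5.79 ± 0.42, adjusted p = 1.78e-06) of the trophectoderm. The same step raised Nanog (4.27 ± 0.32, adjusted p = 2.17e-06) of the pluripotent cells and Gata6 (5.88 ± 0.43, adjusted p = 1.94e-06) of the primitive endoderm. ERK targets moved in both directions. Spry4, a feedback inhibitor of the pathway, fell (-5.18 ± 0.29, adjusted p = 3.55e-07), as did the immediate-early gene Egr1 (-4.43 ± 0.48, adjusted p = 2.56e-05). The ERK phosphatase gene Dusp6 (1.88 ± 0.34, adjusted p = 7.39e-04) and Myc (2.27 ± 0.28, adjusted p = 5.75e-05) rose.

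Of 28 maternal oocyte genes 0 were higher and 27 lower over all genes and adjusted over the list alone (median -4.23, camera adjusted p = 7.78e-13, and adjusted p = 0.0362 with an estimated correlation). Of 54 oxidative phosphorylation genes 43 were higher and 0 lower by either adjustment (adjusted p = 2.18e-10 by camera; adjusted p = 0.0849 with an estimated correlation), Ndufa5 of complex I by 4.93 ± 0.25 (adjusted p = 2.59e-07). Ribosomal protein genes rose in 28 of 30, or 29 adjusted over the list alone, such as Rps6 (3.01 ± 0.27, adjusted p = 7.25e-06). As a list they had adjusted p = 9.50e-08, and adjusted p = 0.390 with an estimated correlation. The trophectoderm list had 13 of 21 higher (adjusted p = 0.00241), the pluripotency list 15 of 22 higher and 2 lower (adjusted p = 0.00950) and the junction list 12 of 22 higher and 3 lower (adjusted p = 0.0146). Each of these lists had adjusted p = 0.390 with an estimated correlation, and adjusted over each list alone the counts were the same. Among junction genes, Cldn4 of the tight junction rose by 5.01 ± 0.56 (adjusted p = 2.87e-05) and Cdh1, the cadherin of compaction, by 3.34 ± 0.31 (adjusted p = 9.25e-06). In all, 5506 of 9930 genes changed, 2785 higher and 2721 lower.

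The step from 4 to 8 cells to morula and blastocyst shows which changes normally come next. Keratin genes of the trophectoderm rose further, Krt8 by 3.82 ± 0.42 (adjusted p = 4.86e-04, n = 2 per group) and Krt18 by 3.78 ± 0.59 (adjusted p = 0.00197). With them rose Cdx2 (2.25 ± 0.35, adjusted p = 0.00207) and Id2 (4.74 ± 0.44, adjusted p = 2.11e-04), an inhibitor of helix-loop-helix factors. Nanog (2.70 ± 0.32, adjusted p = 5.86e-04) and Sox2 (4.06 ± 0.59, adjusted p = 0.00152) of the pluripotent cells rose, whereas Pou5f1 did not pass (0.11 ± 0.46, adjusted p = 0.892). Largest was the rise of Lgals1, a galectin (6.05 ± 0.76, adjusted p = 8.06e-04). Among falls were Foxa1, a pioneer factor (-5.43 ± 0.74, adjusted p = 0.00116), the early embryonic gene Klf17 (-4.57 ± 0.45, adjusted p = 2.79e-04). So were the maternal deadenylation factor Btg4 (-2.89 ± 0.29, adjusted p = 2.85e-04) and Myc (-1.71 ± 0.28, adjusted p = 0.00243). Dusp6 fell by 1.57 ± 0.34 (adjusted p = 0.00882), but not without control day 2.5 replicate 1 (adjusted p = 0.0698) or control day 3.5 replicate 1 (adjusted p = 0.0525). Fos, a partner in the AP-1 factor, did not pass (1.11, adjusted p = 0.0567; adjusted p = 0.0416 with the replicate number as block).

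Maternal genes kept falling at this step (11 of 28 lower and 1 higher, 16 not passed, with the same counts adjusted over the list alone; camera adjusted p = 4.59e-05, and adjusted p = 0.280 with an estimated correlation), Btg4 among them. Trophectoderm markers had 12 of 21 higher by both adjustments (median 1.09, adjusted p = 4.59e-05, and adjusted p = 0.280 with an estimated correlation). Junction genes had 8 of 22 higher and 1 lower, or 9 and 1 adjusted over the list alone (adjusted p = 0.00215, and adjusted p = 0.318 with an estimated correlation). Ezr of the apical membrane (3.90 ± 0.44, adjusted p = 5.22e-04) and Epcam (3.38 ± 0.42) were among them. The ribosome biogenesis list lay lower (median -0.58, adjusted p = 4.59e-05, and adjusted p = 0.567 with an estimated correlation). Only 3 of its 34 genes fell, 1 when adjusted over the list alone, Wdr43 by 2.10 ± 0.35 (adjusted p = 0.00260). Oxidative phosphorylation had 9 of 54 genes higher by either adjustment (adjusted p = 4.24e-04, and adjusted p = 0.318 with an estimated correlation). The glycolytic genes Gapdh (4.14 ± 0.43, adjusted p = 3.21e-04) and Tpi1 (2.72 ± 0.37, adjusted p = 0.00117) rose, although the glycolysis list did not pass (adjusted p = 0.169). In all, 2148 genes changed, 1326 higher and 822 lower, and the count dropped to 1133 without control day 2.5 replicate 1, 1049 without control day 2.5 replicate 2 and 677 without control day 3.5 replicate 1. Median centring of the arrays gave 963 higher of 2123, or 45.4% in place of 61.7%, and moved the median difference of all genes from 0.09 to -0.12.

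How the arrested embryos differed from controls of the same day was asked next. The U0126 arrays were the least alike of any group, with r = 0.955 and a median absolute difference of 0.438 log2 units. Standard errors and p-values of this comparison use the spread pooled over all 6 groups, so they may understate that of the treated embryos. ERK targets did not fall as a group under U0126. Egr1 rose by 2.92 ± 0.48 log2 (adjusted p = 0.00459, n = 2 per group), from 4.27 ± 0.17 to 7.18 ± 1.18 (mean ± SD), or by at least 2.18 counted from a level of 5. Fgf4, the ligand of the inner cell mass that signals through ERK, rose by 2.73 ± 0.37 (adjusted p = 0.00206). Spry4 rose by 1.46 ± 0.29 (adjusted p = 0.00965; adjusted p = 0.0646 without control day 2.5 replicate 2). Fos rose by 1.76 ± 0.37 (adjusted p = 0.0128; at least 0.71 from a level of 5), but not without control day 2.5 replicate 1 (adjusted p = 0.0931) or U0126 day 2.5 replicate 1 (adjusted p = 0.0625). Myc fell (-1.69 ± 0.28, adjusted p = 0.00448), as did Spred1, a pathway inhibitor (-1.74 ± 0.31, adjusted p = 0.00607; adjusted p = 0.0512 without control day 2.5 replicate 1). Dusp6 (-0.80 ± 0.34, adjusted p = 0.147), Ccnd1 (0.76, adjusted p = 0.253) and Etv5 (0.87 ± 0.42, adjusted p = 0.213; adjusted p = 0.0464 with the replicate number as block) did not pass. Of 18 ERK targets 5 were higher, 3 lower and 10 not passed by either adjustment (median 0.85, mean 0.40, camera adjusted p = 0.700). Of 15 ERK cascade components 1 was higher, Fgf4, with a median of 0.01, a mean of 0.10 and a camera direction of down (adjusted p = 0.700).

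Some markers of the first lineages were lower in the arrested embryos. Cdx2, which specifies trophectoderm, fell by 2.99 ± 0.35 (adjusted p = 0.00135, n = 2 per group), from 7.41 ± 0.39 to 4.42 ± 0.12 (at least 2.41 down to a level of 5), and Krt8 by 3.19 ± 0.42 (adjusted p = 0.00199). Of 21 trophectoderm markers 7 were lower and 0 higher, 10 lower adjusted over the list alone (median -0.62, camera adjusted p = 7.70e-05; adjusted p = 0.256 with an estimated correlation). Pluripotency genes had 2 higher and 6 lower of 22, or 3 and 9 adjusted over the list alone (median -0.71, adjusted p = 0.00411; adjusted p = 0.30 with an estimated correlation). The lower genes included Gdf3 (-3.27 ± 0.43, adjusted p = 0.00199), a ligand of the TGF-beta family, and Tfcp2l1 (-3.17 ± 0.38, adjusted p = 0.00135), a factor of naive pluripotency. Nanog fell by 1.49 ± 0.32 (adjusted p = 0.0136), but not without control day 2.5 replicate 1 (adjusted p = 0.0981) or U0126 day 2.5 replicate 1 (adjusted p = 0.0788). Pou5f1 was lower by 1.60 ± 0.46 (adjusted p = 0.0425), but not without control day 2.5 replicate 1 (adjusted p = 0.255) or 2 (adjusted p = 0.0549) or U0126 day 2.5 replicate 1 (adjusted p = 0.0893) or 2 (adjusted p = 0.137). Primitive endoderm markers had 5 of 15 lower by either adjustment (median -0.37, adjusted p = 0.0400; adjusted p = 0.30 with an estimated correlation). The list had adjusted p = 0.0709 with the replicate number as block and adjusted p = 0.0754 after median centring. Among them was Dab2, an endocytic adaptor (-3.35 ± 0.51, adjusted p = 0.00326). Gata6 fell by 1.96 ± 0.43 (adjusted p = 0.0154), but not without control day 2.5 replicate 1 (adjusted p = 0.107) or U0126 day 2.5 replicate 2 (adjusted p = 0.0745). Junction genes had 6 of 22 lower, 8 adjusted over the list alone (median -0.48, adjusted p = 9.13e-04; adjusted p = 0.284 with an estimated correlation). Among them, Cldn4 was lower by 3.02 ± 0.56 (adjusted p = 0.00729; adjusted p = 0.0639 without control day 2.5 replicate 1).

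**Figure D2:**
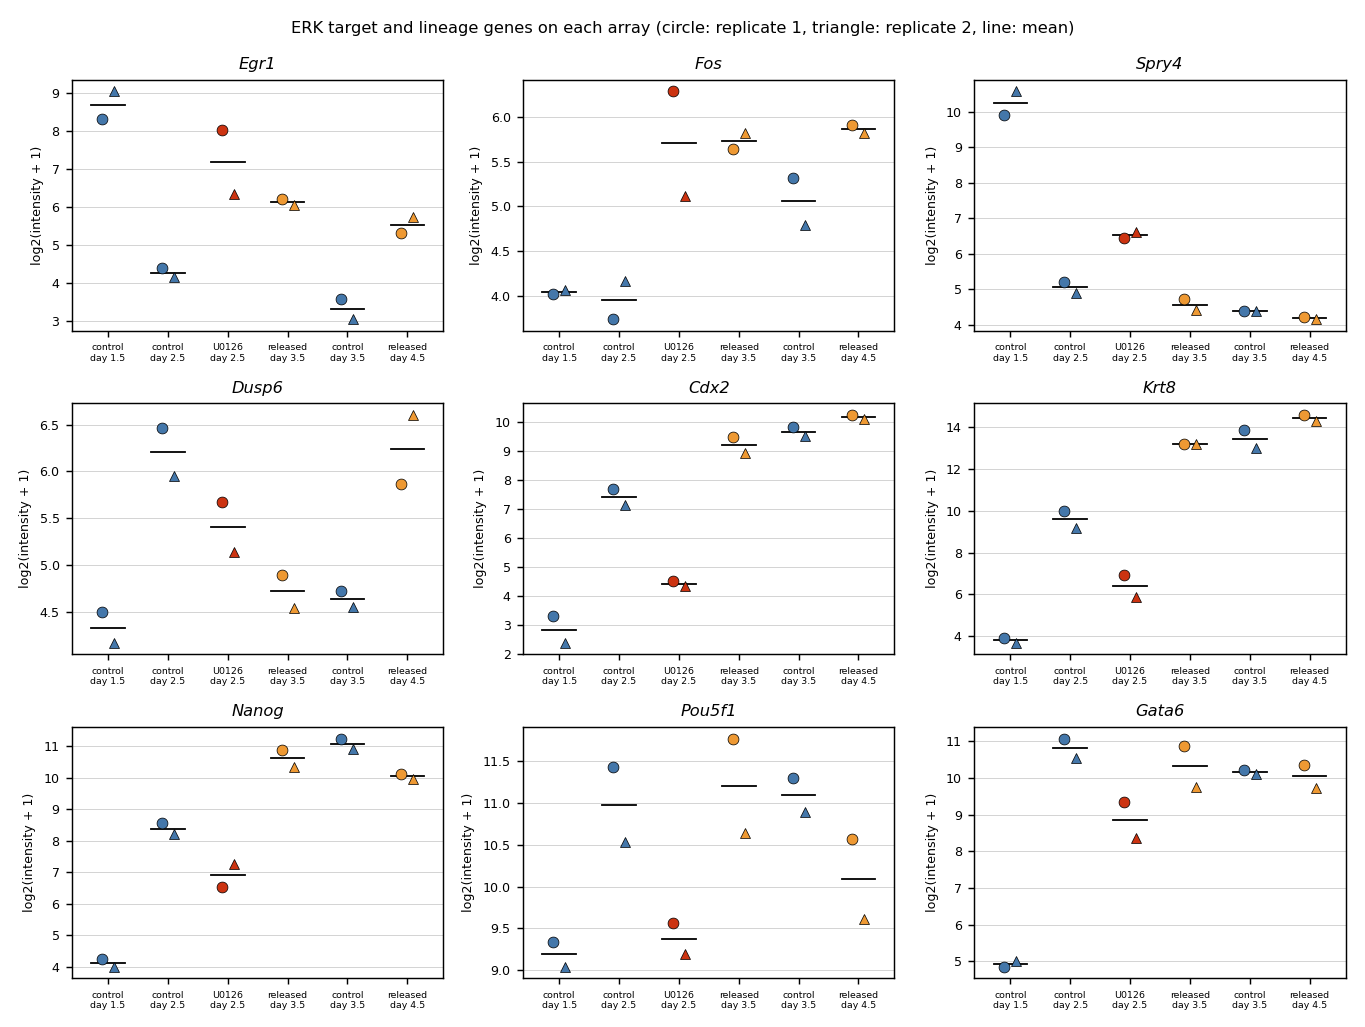
Level (log2 of intensity + 1) of ERK targets and lineage genes on each array of the 6 groups. Circles mark replicate 1, triangles replicate 2 and lines the mean, which for Cdx2 was 4.42 under U0126 and 7.41 in control day 2.5 embryos.

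Some maternal transcripts were higher under U0126. Of 28 maternal genes 10 were higher and 0 lower, 12 higher adjusted over the list alone (median 0.85, camera adjusted p = 1.22e-04; adjusted p = 0.256 with an estimated correlation). Btg4 was among them (2.46 ± 0.29, adjusted p = 0.00135). Genes that normally fall from 2 cells to blastocyst had 577 of 2869 higher and 27 lower (median 0.50, camera p = 4.22e-15; p = 7.88e-05 with an estimated correlation). Genes that normally rise had 125 of 3485 higher and 351 lower (median -0.16, camera p = 1.06e-12; p = 0.00721 with an estimated correlation), against a median of 0.13 for all other genes. The median of the rising genes was -0.253 without U0126 day 2.5 replicate 1, -0.0603 without U0126 day 2.5 replicate 2 and -0.383 after median centring, which gave 0.269 for the falling genes. The 11 genes of the 2-cell list had 1 higher, 0 adjusted over the list alone (adjusted p = 0.927). This was Zfp352 (2.81 ± 0.79, adjusted p = 0.0399). It did not pass without control day 2.5 replicate 1 (adjusted p = 0.0580), control day 2.5 replicate 2 (adjusted p = 0.228), U0126 day 2.5 replicate 1 (adjusted p = 0.111) or U0126 day 2.5 replicate 2 (adjusted p = 0.113).

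Among the largest rises was Rgs9bp, an anchor of a regulator of G-protein signalling (5.06 ± 0.36, adjusted p = 2.24e-04, n = 2 per group), from 3.57 ± 0.12 to 8.63 ± 0.86. It was followed by the growth arrest gene Gadd45g (4.61 ± 0.54, adjusted p = 0.00135), Ipcef1, a partner of an ARF exchange factor (4.39 ± 0.56, adjusted p = 0.00171), the amino acid transporter gene Slc43a2 (4.23 ± 0.60, adjusted p = 0.00252) and the clock-output factor Dbp (4.06 ± 0.58, adjusted p = 0.00244). Bnc1, a zinc-finger factor (3.91 ± 0.32, adjusted p = 2.68e-04), Tmprss11a (3.72 ± 0.31, adjusted p = 2.68e-04) and Rgs17 (3.69 ± 0.41, adjusted p = 0.00109) completed the 8 largest. Of these, Ipcef1, Bnc1, Tmprss11a and Rgs17 stood at 10.36, 10.07, 11.31 and 10.04 in control day 1.5 embryos, above their levels under U0126. Of these genes only Dbp exceeded a level of 5 on a control day 2.5 array, and counted from that level the rise was at least 3.63 for Rgs9bp, 3.13 for Gadd45g, 2.12 for Ipcef1, 3.19 for Slc43a2, 2.03 for Bnc1, 3.23 for Tmprss11a and 1.89 for Rgs17, so their order is uncertain. The largest falls were those of the tetraspanin Tspan1 (-4.62 ± 0.62, adjusted p = 0.00206), the actin nucleator Diaph2 (-4.39 ± 0.49, adjusted p = 0.00109). Next came the reductase Akr1b8 (-4.35 ± 0.41, adjusted p = 6.27e-04) and Dennd1b (-4.22 ± 0.31, adjusted p = 2.24e-04). Under U0126, Diaph2, Akr1b8 and Dennd1b lay under 5 on both arrays, so that their falls were at least 2.75, 3.21 and 2.70 and their order is uncertain. In all, 1384 genes passed, 915 higher and 469 lower. That count was 409 without control day 2.5 replicate 1, 575 without control day 2.5 replicate 2 and 809 without U0126 day 2.5 replicate 1. With only these 4 arrays limma gave 0, with 2245 genes at an unadjusted p under 0.05. The median difference of all genes was 0.11, and median centring moved it to -0.09 and the split to 553 higher of 1177, or 47.0% in place of 66.1%.

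Lists of the cell cycle, stress, metabolism and chromatin were examined next. S phase genes had 1 higher and 1 lower of 32, or 0 and 1 adjusted over the list alone, with a median of 0.03, a mean of -0.05 and a camera direction of down. Mitosis genes had 2 of 31 higher (adjusted p = 0.393). The list of p53 targets and cell cycle inhibitors had 5 higher and 3 lower of 24, or 6 and 3 adjusted over the list alone (adjusted p = 0.295). Gadd45a was higher (2.07 ± 0.32, adjusted p = 0.00342), and Cdkn1a, the inhibitor p21, did not pass (-0.18 ± 0.33, adjusted p = 0.786). Stress genes had 3 of 23 higher, 5 adjusted over the list alone, with a median of -0.07, a mean of 0.35 and a camera direction of up (adjusted p = 0.700). Of 30 ribosomal protein genes 1 was lower, 0 adjusted over the list alone, but the list lay lower (median -0.21, adjusted p = 0.00762; adjusted p = 0.710 with an estimated correlation). None of 34 ribosome biogenesis genes passed, nor did any of 54 oxidative phosphorylation genes (adjusted p = 0.0979; adjusted p = 0.0448 after median centring). Glycolysis had 1 of 17 lower, with a median of 0.35, a mean of 0.03 and a camera direction of down (adjusted p = 0.700). Cholesterol synthesis had 3 of 19 lower, with a median of 0.24 and a mean of -0.16 (adjusted p = 0.295). The chromatin regulators had 2 higher and 3 lower of 23, or 3 and 3 adjusted over the list alone, with the DNA methyltransferase gene Dnmt3b lower (-1.74 ± 0.27, adjusted p = 0.00336). Of markers of other cell types, Amhr2 of granulosa cells (0.68 ± 0.27, adjusted p = 0.128) and Ovgp1 (0.69 ± 0.56, adjusted p = 0.481) and Wfdc2 (0.43, adjusted p = 0.637) of the oviduct did not pass. Cd68, a lysosomal protein of macrophages, was higher (2.43 ± 0.40, adjusted p = 0.00452). Of 2 sperm genes, Odf2 of the flagellum was higher (1.29 ± 0.36, adjusted p = 0.0398), but not without control day 2.5 replicate 1 (adjusted p = 0.269) or U0126 day 2.5 replicate 1 (adjusted p = 0.157) or 2 (adjusted p = 0.0652).

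**Figure D3:**
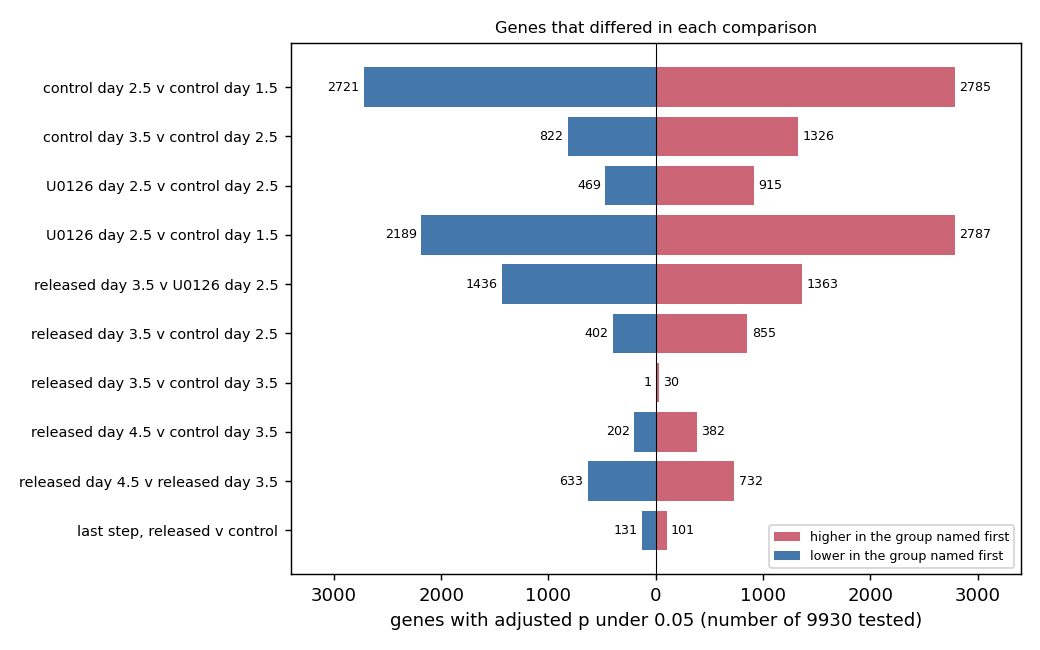
Number of genes higher and lower in each comparison at an adjusted p under 0.05, of 9930 tested. The count was 1384 for U0126-treated against control day 2.5 embryos and 31 for released against control day 3.5 embryos.

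Arrested embryos were also compared with 2-cell embryos, to ask how far they had moved from the stage before treatment. Most of the turnover had taken place, with Tcl1 lower by 6.65 ± 0.26 (adjusted p = 2.80e-07, n = 2 per group). Also lower were the related Tcl1b1 by 6.94 ± 0.23 (adjusted p = 1.53e-07) and Wee2 by 6.81 ± 0.70 (adjusted p = 2.65e-05). Vnn1 (7.57 ± 0.51, adjusted p = 2.60e-06), the syntaxin Stx3 (6.03 ± 0.36, adjusted p = 1.14e-06) and Acadl of fatty acid oxidation (5.99 ± 0.30, adjusted p = 6.24e-07) rose most. Spry4 was lower (-3.72 ± 0.29, adjusted p = 4.76e-06) and Fos higher (1.66 ± 0.37, adjusted p = 0.00360). Higher too were Nanog (2.78 ± 0.32, adjusted p = 5.61e-05) and Cdkn1a (2.07 ± 0.33, adjusted p = 4.79e-04). Egr1 was lower by 1.51 (adjusted p = 0.0238), but not without control day 1.5 replicate 2 (adjusted p = 0.156) or U0126 day 2.5 replicate 2 (adjusted p = 0.191). Maternal genes had 26 of 28 lower by either adjustment (median -3.40, camera adjusted p = 8.73e-14, and adjusted p = 0.0301 with an estimated correlation). Oxidative phosphorylation had 40 of 54 higher, 41 adjusted over the list alone (adjusted p = 2.86e-10, and adjusted p = 0.0872 with an estimated correlation). Ribosomal proteins had 25 of 30 higher, or 26 (adjusted p = 1.97e-06, and adjusted p = 0.501 with an estimated correlation). In all, 4976 genes changed, 2787 higher and 2189 lower, around a median difference of all genes of 0.18 that median centring moved to 0.02.

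Some genes under U0126 lay outside the range of both control groups. Rgs9bp was 5.06 above control day 2.5 and 5.30 above control day 1.5 embryos and Gadd45g 4.61 and 4.16, both from control levels under 5, and Dbp 4.06 and 3.32, while the glucose transporter gene Slc2a1 was lower by 2.54 and 3.11. Slc2a1 did not pass against control day 2.5 without control day 2.5 replicate 1 (adjusted p = 0.0729) or replicate 2 (adjusted p = 0.0524). Higher than both were 265 genes, where independent lists give 257, and lower than both were 75, where independent lists give 103. Simulated data gave 0, but all genes were unchanged there and hardly any could be called, so that 0 is no measure for these counts. Part of any excess may come from the shared U0126 arrays.

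What followed release was asked by comparing released day 3.5 with arrested embryos. The trophectoderm keratins Krt8 (6.77 ± 0.42, adjusted p = 1.10e-05, n = 2 per group) and Krt18 (6.44 ± 0.59, adjusted p = 7.99e-05) were among the largest rises. So were the small heat-shock protein gene Cryab (6.50 ± 0.42, adjusted p = 1.35e-05) and Akr1b8 (7.44 ± 0.41, adjusted p = 1.04e-05). Cdx2 (4.76 ± 0.35, adjusted p = 2.35e-05) and Nanog (3.73 ± 0.32, adjusted p = 5.49e-05) rose. Spry4 fell (-1.95 ± 0.29, adjusted p = 9.61e-04), and Fos did not pass (0.03, adjusted p = 0.969). Egr1 did not pass (-1.06 ± 0.48, adjusted p = 0.126; adjusted p = 0.00949 without U0126 day 2.5 replicate 2). The largest falls were those of Gdap1 (-5.79 ± 0.55, adjusted p = 1.06e-04) of the mitochondrial outer membrane, Accsl (-5.62 ± 0.45), Klhl8 (-5.54 ± 0.32, adjusted p = 1.04e-05) and Trim61 (-5.44 ± 0.42). Counted from a level of 5, the differences were at least 6.30 for Akr1b8, 5.29 for Cryab, 4.31 for Accsl, 3.98 for Klhl8 and 3.90 for Trim61.

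Trophectoderm markers had 16 of 21 higher in this comparison, 17 adjusted over the list alone (median 1.76, camera adjusted p = 8.20e-10; adjusted p = 0.0822 with an estimated correlation). Junction genes had 12 of 22 higher, or 16 (adjusted p = 1.39e-06; adjusted p = 0.0822 with an estimated correlation). Maternal genes had 2 higher and 16 lower of 28, or 2 and 18 (adjusted p = 3.11e-06; adjusted p = 0.0822 with an estimated correlation). Primitive endoderm markers had 7 of 15 higher and 1 lower, or 8 and 1 (adjusted p = 0.00336; adjusted p = 0.138 with an estimated correlation). Oxidative phosphorylation had 11 of 54 higher, or 10 (adjusted p = 1.16e-05; adjusted p = 0.138 with an estimated correlation). Of 11 genes of the 2-cell list 5 were higher, or 6 (median 1.72, adjusted p = 0.0461; adjusted p = 0.515 with an estimated correlation, and adjusted p = 0.0804 with the replicate number as block). Tcstv1, Tcstv3 and Usp17la were among the 5, and Zfp352 (adjusted p = 0.343) and Tdpoz1 (adjusted p = 0.0685) did not pass. The list also holds heat-shock genes. Hspa1a lay at 6.09 and 4.57 in arrested and 7.67 and 6.75 in released embryos, Hspa1b at 8.81 and 8.41 against 10.44 and 10.23. Hspa1b was about as high in control day 3.5 (8.90 and 10.43) as in control day 1.5 embryos (9.60 and 10.18). Eif1a and Eif1ax were lower in control day 1.5 than in later control embryos. Glycolysis had 6 of 17 higher and 1 lower by either adjustment (adjusted p = 0.00626; adjusted p = 0.441 with an estimated correlation). Ribosome biogenesis had 5 of 34 lower, or 2 (adjusted p = 0.0461; adjusted p = 0.777 with an estimated correlation). In all, 2799 genes changed, 1363 higher and 1436 lower, but 1758 without released day 3.5 replicate 1, 1630 without released day 3.5 replicate 2 and 1381 with only the arrays compared.

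Released day 3.5 embryos were set against control day 2.5 embryos, which the series text places at a similar cell number. They were far ahead in trophectoderm keratins, Krt8 by 3.59 ± 0.42 (adjusted p = 0.00135, n = 2 per group) and Krt18 by 3.68 ± 0.59 (adjusted p = 0.00484). They were ahead as well in Id2 (3.55 ± 0.44, adjusted p = 0.00164), Nanog (2.24 ± 0.32, adjusted p = 0.00289) and Lgals1 (5.34 ± 0.76, adjusted p = 0.00289). Cdx2 was higher (1.77 ± 0.35, adjusted p = 0.0111), but not without control day 2.5 replicate 2 (adjusted p = 0.0858) or released day 3.5 replicate 1 (adjusted p = 0.0708). The basement membrane genes Col4a2 (2.92 ± 0.40, adjusted p = 0.00229) and Sparc (2.65 ± 0.39, adjusted p = 0.00343) and the heme oxygenase gene Hmox1 (3.51 ± 0.48, adjusted p = 0.00247) were higher. Lower were Btg4 (-2.37 ± 0.29, adjusted p = 0.00156), Spred1 (-2.16 ± 0.31, adjusted p = 0.00279) and Dynap (-4.43 ± 0.32, adjusted p = 4.15e-04), an activator of Akt. Egr1 was higher by 1.85 ± 0.48 (adjusted p = 0.0324), but not without control day 2.5 replicate 1 (adjusted p = 0.0953) or 2 (adjusted p = 0.152) or released day 3.5 replicate 1 (adjusted p = 0.128) or 2 (adjusted p = 0.120). Cdkn1a did not pass (1.12, adjusted p = 0.0515; adjusted p = 0.0283 with the replicate number as block).

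Genes that normally rise from 2 cells to blastocyst had 575 of 3485 higher and 34 lower in this comparison (median 0.47, camera p = 1.69e-15; p = 0.00428 with an estimated correlation). Genes that normally fall had 123 of 2869 higher and 263 lower (median -0.20, camera p = 1.91e-11; p = 1.90e-04 with an estimated correlation), against a median of 0.03 for other genes. Median centring gave medians of 0.292 and -0.384, and a pseudocount of 16 gave -0.0978 for the falling genes. Trophectoderm markers had 10 of 21 higher, 13 adjusted over the list alone (median 1.77, adjusted p = 2.30e-06; adjusted p = 0.295 with an estimated correlation). Junction genes had 7 of 22 higher, or 8 with 1 lower (adjusted p = 0.00225; adjusted p = 0.295 with an estimated correlation). Ezr (3.15 ± 0.44, adjusted p = 0.00254) and Epcam (3.05 ± 0.42, adjusted p = 0.00240) were among them. Maternal genes had 2 higher and 4 lower of 28, or 3 and 5 (adjusted p = 0.00225; adjusted p = 0.295 with an estimated correlation). Oxidative phosphorylation had 4 of 54 higher, or 2 (adjusted p = 2.08e-04; adjusted p = 0.295 with an estimated correlation). Glycolysis had 6 of 17 higher, or 9 (median 1.52, adjusted p = 0.00251; adjusted p = 0.311 with an estimated correlation), with Gapdh higher by 3.77 ± 0.43 (adjusted p = 0.00124). The p53 list had 6 of 24 higher, or 10 (adjusted p = 0.0147; adjusted p = 0.311 with an estimated correlation). The 2-cell list had 5 of 11 higher by either adjustment (adjusted p = 0.0242; adjusted p = 0.370 with an estimated correlation). The primitive endoderm list had 4 of 15 higher and 1 lower, or 7 and 2 (adjusted p = 0.0417; adjusted p = 0.311 with an estimated correlation). Both had adjusted p = 0.0674 with the replicate number as block. Ribosome biogenesis lay lower (median -0.44, adjusted p = 2.08e-04; adjusted p = 0.378 with an estimated correlation), with 1 of 34 genes passing and 0 adjusted over the list alone.

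In all, 1257 genes differed between released day 3.5 and control day 2.5 embryos, 855 higher and 402 lower, or 2018 with the replicate number as block. The count was 531 without control day 2.5 replicate 1, 337 without control day 2.5 replicate 2, 577 without released day 3.5 replicate 1 and 268 without released day 3.5 replicate 2. Median centring gave 607 higher of 1193, or 50.9% in place of 68.0%, and moved the median difference of all genes from 0.09 to -0.11. Laptm5, a lysosomal gene of blood cells, was higher by 4.60 ± 0.46 (adjusted p = 8.34e-04) and rose by 4.82 ± 0.46 from control day 2.5 to control day 3.5 embryos (adjusted p = 2.47e-04). Wfdc2, a protease inhibitor of the oviduct list, was higher by 2.92 ± 0.50 (adjusted p = 0.00631; adjusted p = 0.0547 without released day 3.5 replicate 2) and rose by 3.23 ± 0.50 at that control step (adjusted p = 0.00195). Amhr2 of granulosa cells was lower by 1.49 ± 0.27 (adjusted p = 0.00840), but not without control day 2.5 replicate 2 (adjusted p = 0.0649) or released day 3.5 replicate 2 (adjusted p = 0.0730). Odf2 of sperm was higher by 1.39 ± 0.36 (adjusted p = 0.0321), but not without control day 2.5 replicate 1 (adjusted p = 0.202) or released day 3.5 replicate 1 (adjusted p = 0.0650) or 2 (adjusted p = 0.182).

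Embryos of the same day but different cell number, released and control day 3.5, were then compared. Some genes of the 2-cell stage were higher in released embryos. Zfp352, a zinc-finger gene of the 2-cell embryo, was higher by 6.11 ± 0.79 (adjusted p = 0.0102, n = 2 per group), at 9.62 ± 0.17 against 3.51 ± 0.79. Tcstv1 was higher by 5.67 ± 0.72 (adjusted p = 0.0102), Tcstv3 by 6.12 ± 0.90 (adjusted p = 0.0234) and the deubiquitinase gene Usp17la by 6.81 ± 1.02 (adjusted p = 0.0234). All 4 lay under 5 in control day 3.5 embryos, and from that level the difference was at least 4.62 for Zfp352 and 4.85 for Usp17la. Zfp352 lost its call without control day 3.5 replicate 1 (adjusted p = 0.215), released day 3.5 replicate 1 (adjusted p = 0.0566) or replicate 2 (adjusted p = 0.124). For control day 3.5 replicate 1 and 2 and released day 3.5 replicate 1 and 2 in turn, adjusted p was 0.161, 0.0503, 0.0566 and 0.122 for Tcstv1, 0.301, 0.0804, 0.0785 and 0.181 for Tcstv3, and 0.301, 0.0893, 0.0566 and 0.181 for Usp17la. Egr1 was higher by 2.82 ± 0.48 (adjusted p = 0.0471, but 0.301, 0.168, 0.232 and 0.204 in the same order). Acss1, an acetyl-CoA synthetase of mitochondria, was the only lower gene (-2.25 ± 0.33, adjusted p = 0.0234). It did not pass without control day 3.5 replicate 1 (adjusted p = 0.260), released day 3.5 replicate 1 (adjusted p = 0.104) or replicate 2 (adjusted p = 0.181). Cdx2 (-0.47, adjusted p = 0.968), Nanog (-0.46, adjusted p = 0.948) and Cdkn1a (1.62, adjusted p = 0.0888) did not pass.

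Of the 11 genes of the 2-cell list 4 were higher in this comparison and 6 adjusted over the list alone (median 2.66, camera adjusted p = 6.29e-12; adjusted p = 0.0721 with an estimated correlation). The p53 list had 0 of 24 past the test but 9 higher adjusted over the list alone (median 0.73, adjusted p = 7.45e-08; adjusted p = 0.0769 with an estimated correlation). The maternal list had 0 of 28, or 7 higher and 1 lower (median 0.18, adjusted p = 4.32e-05; adjusted p = 0.129 with an estimated correlation). Glycolysis had 0 of 17, or 1 higher (adjusted p = 0.0120; adjusted p = 0.467 with an estimated correlation). Trophectoderm markers did not pass as a list (adjusted p = 0.667), nor did ribosome biogenesis genes (adjusted p = 0.149; adjusted p = 0.0355 with the replicate number as block). In all, 31 genes differed, 30 higher and 1 lower, with 699 at an unadjusted p under 0.05. The count was 1 without control day 3.5 replicate 1, 15 without released day 3.5 replicate 1, 6 without released day 3.5 replicate 2 and 13 with only the arrays compared.

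**Figure D4:**
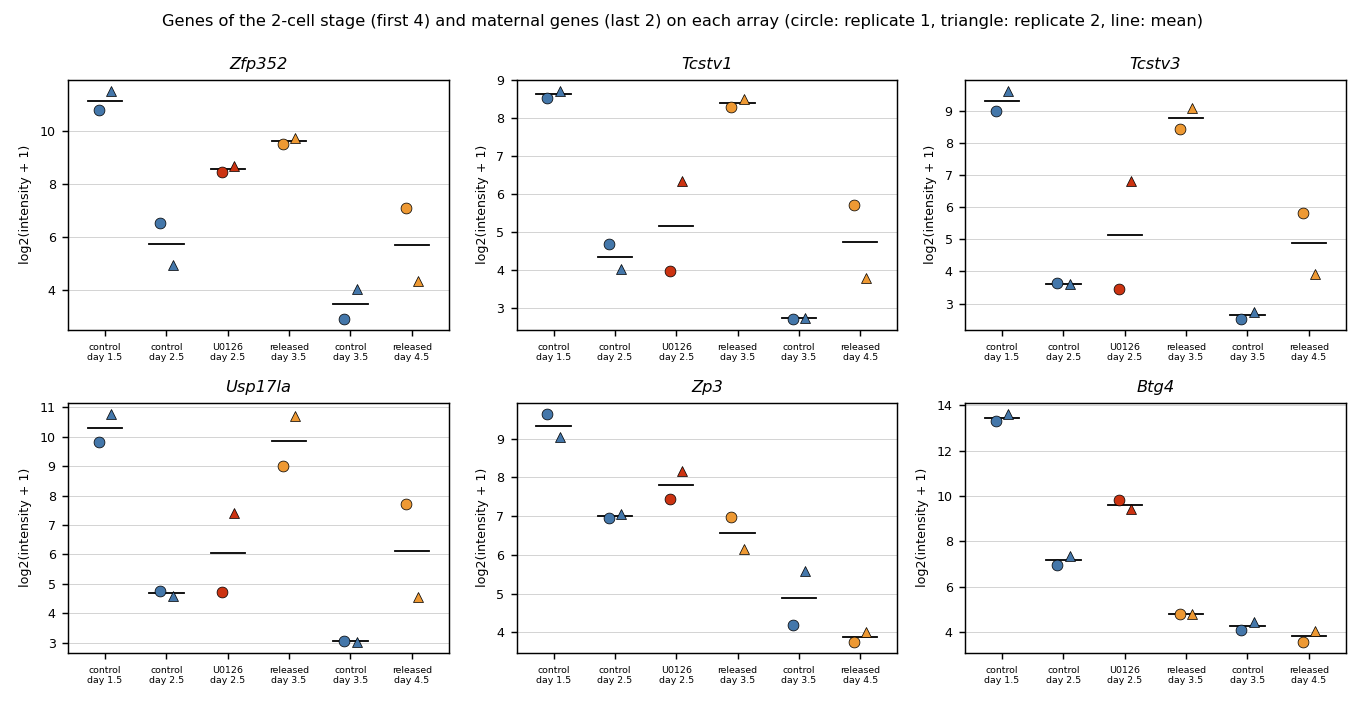
Level (log2 of intensity + 1) of 4 genes of the 2-cell stage and of the maternal genes Zp3 and Btg4 on each array of the 6 groups. The mean of Zfp352 was 9.62 in released and 3.51 in control day 3.5 embryos.

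Released day 4.5 embryos were compared with control day 3.5 embryos, which the series text places at the same stage. Some trophectoderm and primitive endoderm markers were higher. Elf5, a factor of the trophoblast, was at 8.94 ± 1.12 against 2.75 ± 0.03 (difference 6.19 ± 0.42, adjusted p = 6.48e-05, n = 2 per group), or at least 3.94 from a level of 5. The placental gene Plac1 was higher by 4.47 ± 0.35 (adjusted p = 1.42e-04), the trophoblast factor Gata2 by 3.96 ± 0.47 (adjusted p = 0.00165) and the endoderm factor Sox17 by 4.14 ± 0.51 (adjusted p = 0.00190). Dmkn (5.87 ± 0.38, adjusted p = 6.48e-05), an epidermal secreted protein, the peptide transporter Slc15a2 (5.31 ± 0.55) and Gulp1 (4.48 ± 0.53, adjusted p = 0.00162), an adaptor of engulfment, rose as well. From a level of 5 the difference was at least 3.21 for Plac1, 2.43 for Sox17 and 5.29 for Dmkn. Lower were Tent5c, a poly(A) polymerase (-3.60 ± 0.45, adjusted p = 0.00196), and Stmn3, a tubulin-binding protein (-3.34 ± 0.37). Dusp6 was higher by 1.60 ± 0.34 (adjusted p = 0.0211), but not without control day 3.5 replicate 1 (adjusted p = 0.0565) or 2 (adjusted p = 0.183) or released day 4.5 replicate 2 (adjusted p = 0.187). Egr1 was higher by 2.22 ± 0.48 (adjusted p = 0.0252), but not without control day 3.5 replicate 2 (adjusted p = 0.240) or released day 4.5 replicate 1 (adjusted p = 0.0887) or 2 (adjusted p = 0.180). Of the markers of other cell types, Wfdc2 was higher by 2.15 ± 0.50 (adjusted p = 0.0317), but not without control day 3.5 replicate 2 (adjusted p = 0.310) or released day 4.5 replicate 1 (adjusted p = 0.164) or 2 (adjusted p = 0.132). Laptm5 was higher by 1.85 ± 0.46 (adjusted p = 0.0435), but not without control day 3.5 replicate 1 (adjusted p = 0.0588) or 2 (adjusted p = 0.351) or released day 4.5 replicate 1 (adjusted p = 0.215) or 2 (adjusted p = 0.144). Nanog (-1.04 ± 0.32, adjusted p = 0.0889), Cdx2 (0.50 ± 0.35, adjusted p = 0.476) and Pou5f1 (-1.0 ± 0.46, adjusted p = 0.246; adjusted p = 0.0446 with the replicate number as block) did not pass.

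Trophectoderm markers had 8 of 21 higher here, or 15 with 1 lower adjusted over the list alone (median 1.24, camera adjusted p = 2.51e-10; adjusted p = 0.100 with an estimated correlation). Primitive endoderm markers had 4 of 15 higher, or 5 (adjusted p = 1.87e-04; adjusted p = 0.106 with an estimated correlation), Sparc by 2.66 ± 0.39 (adjusted p = 0.00443) among them. Oxidative phosphorylation had 2 of 54 higher by either adjustment (median 0.51, adjusted p = 7.54e-08; adjusted p = 0.106 with an estimated correlation). Junction genes had 2 of 22 higher (adjusted p = 2.92e-04; adjusted p = 0.186 with an estimated correlation). The cholesterol list had 2 of 19 higher (adjusted p = 0.00113), the p53 list 1 of 24 (adjusted p = 0.0111) and the S phase list 0 of 32 (median -0.39, adjusted p = 0.0241). Each had adjusted p = 0.355 with an estimated correlation. Ribosome biogenesis lay lower with 1 of 34 genes past the test (median -0.71, adjusted p = 1.72e-06; adjusted p = 0.428 with an estimated correlation). Glycolysis had 3 of 17 higher, or 4 (adjusted p = 0.0474; adjusted p = 0.481 with an estimated correlation).

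Genes that rose from 2 cells to 4 to 8 cells did not pass as a set in released day 4.5 embryos (median -0.12, camera p = 0.0561; p = 0.280 with an estimated correlation). Of 2785 such genes, 76 were higher and 83 lower. Nor did genes that fell (median 0.04, camera p = 0.0901; p = 0.211 with an estimated correlation), with 105 of 2721 higher and 29 lower. The median of other genes was -0.05. The rising set passed camera at the preset correlation without control day 1.5 replicate 1 (median -0.13, p = 0.0217) or control day 3.5 replicate 1 (median -0.08, p = 0.0395). So did the falling set, at that correlation, without control day 1.5 replicate 1 (median 0.05, p = 0.0467) or released day 4.5 replicate 1 (median 0.04, p = 0.0465). In all, 584 genes differed between released day 4.5 and control day 3.5 embryos, 382 higher and 202 lower, or 1017 with the block. The count was 84 without control day 3.5 replicate 2, 150 without released day 4.5 replicate 1 and 127 without released day 4.5 replicate 2.

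The final step of released embryos, from day 3.5 to day 4.5, brought Elf5 (5.78 ± 0.42, adjusted p = 9.92e-05, n = 2 per group) and Slc15a2 (6.14 ± 0.55, adjusted p = 2.40e-04) up. With them rose the alcohol dehydrogenase gene Adh1 (6.58 ± 0.85, adjusted p = 0.00126) and Sox17 (3.78 ± 0.51, adjusted p = 0.00154). Obox6, a homeobox gene of early embryos (-4.59 ± 0.63, adjusted p = 0.00155), and Tent5c (-4.41 ± 0.45, adjusted p = 4.96e-04) fell. Cdx2 (0.98, adjusted p = 0.0931; adjusted p = 0.0212 with the block) and Pou5f1 (-1.12, adjusted p = 0.134; adjusted p = 0.0181 with the block) passed only with the replicate number as block. The 2-cell list fell in 8 of 11 genes, 9 adjusted over the list alone (median -2.35, camera adjusted p = 1.18e-05; adjusted p = 0.139 with an estimated correlation). Its heat-shock genes Hspa1a and Hspa1b were also lower on both released day 4.5 arrays than on both released day 3.5 arrays. Trophectoderm markers rose in 12 of 21, or 16 with 1 lower (adjusted p = 4.98e-09; adjusted p = 0.137 with an estimated correlation). Maternal genes had 1 higher and 8 lower of 28 (adjusted p = 8.21e-04), and primitive endoderm markers 4 of 15 higher (adjusted p = 0.00639). Junction genes had 5 of 22 higher, or 6 (adjusted p = 3.76e-04), and oxidative phosphorylation 5 of 54, or 3 (adjusted p = 9.76e-07). These 4 lists each had adjusted p = 0.139 with an estimated correlation. Ribosome biogenesis fell in 7 of 34 genes, or 13 (median -0.85, adjusted p = 9.76e-07), and cholesterol synthesis rose in 4 of 19, or 8 (adjusted p = 0.00310), both with adjusted p = 0.365 with an estimated correlation. In all, 1365 genes changed, 732 higher and 633 lower, or 2165 with the block. The count was 400 without released day 3.5 replicate 1, 759 without released day 3.5 replicate 2, 663 without released day 4.5 replicate 1 and 321 without released day 4.5 replicate 2.

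Whether that step differed from the step of controls from day 2.5 to day 3.5 was tested by the interaction. The steps did not start alike, with positions of 0.774 in control day 2.5 and 0.932 in released day 3.5 embryos. Nanog averaged 8.39 in control day 2.5, 10.63 in released day 3.5 and 11.09 in control day 3.5 embryos. Lama3 averaged 2.90, 6.37 and 7.28 in the same order. A difference between steps can thus come from unlike starting levels. Elf5 rose by 5.78 in released and changed by 0.25 in control embryos (difference 5.53 ± 0.60, adjusted p = 0.00393, n = 2 per group). It lay under 5 on all arrays but those of released day 4.5, so its control step says little and its released step was at least 3.94. The laminin gene Lama3 changed by -0.42 and 4.38 (difference -4.80 ± 0.41, adjusted p = 0.00117) and Hmox1 by -2.64 and 2.26 (difference -4.90 ± 0.69, adjusted p = 0.00959). From a level of 5 the control step of Lama3 was at least 2.28 and the released fall of Hmox1 at least 1.22, while Hmox1 averaged under 5 in both control groups. Nanog changed by -0.58 in released and 2.70 in control embryos (difference -3.27 ± 0.45, adjusted p = 0.00924; adjusted p = 0.0518 without released day 4.5 replicate 2). Dusp6 changed by 1.52 and -1.57 (difference 3.09 ± 0.47, adjusted p = 0.0129). It did not pass without control day 3.5 replicate 2 (adjusted p = 0.0589), released day 3.5 replicate 2 (adjusted p = 0.0510) or released day 4.5 replicate 2 (adjusted p = 0.0681). Gulp1 changed by 5.10 and 0.94 (difference 4.16 ± 0.74, adjusted p = 0.0211), but it averaged under 5 in both control groups and its released step was at least 3.68. Its call was lost without control day 2.5 replicate 1 (adjusted p = 0.0650) or 2 (adjusted p = 0.0679), control day 3.5 replicate 2 (adjusted p = 0.0617), released day 3.5 replicate 1 (adjusted p = 0.0740) or released day 4.5 replicate 2 (adjusted p = 0.0918). Sox17 changed by 3.78 and 0.03 (difference 3.76 ± 0.73, adjusted p = 0.0277), but it too lay under 5 in both control groups, and its released step was at least 2.43. It did not pass without control day 2.5 replicate 1 (adjusted p = 0.0660) or 2 (adjusted p = 0.0971), control day 3.5 replicate 1 (adjusted p = 0.0662) or 2 (adjusted p = 0.0937), released day 3.5 replicate 1 (adjusted p = 0.0877), or released day 4.5 replicate 1 (adjusted p = 0.0502) or 2 (adjusted p = 0.120). Cdx2 did not pass (-1.27, adjusted p = 0.212).

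No list passed the interaction by camera, with a smallest adjusted p of 0.176. Of 22 pluripotency genes 4 had a more positive step in released embryos, with Tdgf1, a co-receptor of Nodal, at 3.15, and 1 a more negative step. Of 18 ERK targets 2 had a more positive step, or 3 adjusted over the list alone. In all, 232 genes differed in the interaction, 101 with a more positive and 131 with a more negative step in released embryos, or 615 with the block. The count was 80 and 52 without control day 2.5 replicate 1 and 2, and 115 and 37 without control day 3.5 replicate 1 and 2. It was 83 and 72 without released day 3.5 replicate 1 and 2, and 81 and 30 without released day 4.5 replicate 1 and 2. Median centring gave 141 more positive of 251, or 56.2% in place of 43.5%, and moved the median of all genes from -0.13 to 0.04.

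**Figure D5:**
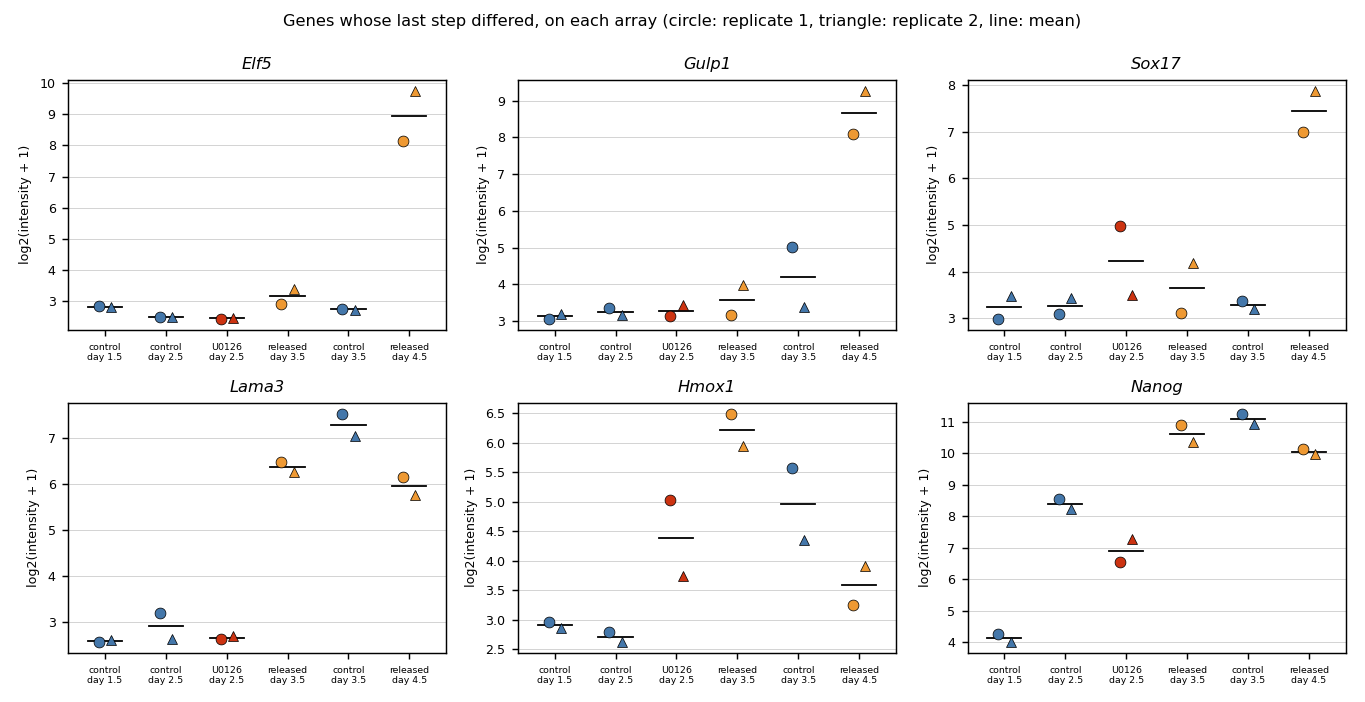
Level (log2 of intensity + 1) of 6 genes with a different final step in released and control embryos, on each array. The mean of Elf5 was 8.94 in released day 4.5 and 2.75 in control day 3.5 embryos.

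The 3′ and 5′ control probes of actin and GAPDH, a sign of RNA degradation, did not move alike in all groups. The actin gap between 3′ and 5′ ends, in log2 units, averaged 4.30 in control day 1.5, 3.86 in control day 2.5 and 4.09 in U0126-treated embryos. It averaged 3.48 in released day 3.5, 3.25 in control day 3.5 and 2.93 in released day 4.5 embryos (n = 2 each). It was larger on replicate 2 in 6 of 6 groups, by 0.91 to 1.85. The GAPDH gap averaged 3.71, 3.12, 2.94, 3.25, 3.29 and 3.20 in the same groups and order, and was larger on replicate 2 in 3 of 6 groups. In the other groups, control day 1.5, control day 2.5 and U0126, the GAPDH 5′ signal was low, from 4.32 to 6.36. It lay from 7.96 to 10.49 where the gap was larger on replicate 2. A gap read from signal near a level of 5 is uncertain and may hide a difference. Amhr2, the granulosa marker, fell by 1.21 ± 0.27 (adjusted p = 0.00325) and by 2.65 ± 0.27 (adjusted p = 3.21e-04) at the control steps from day 1.5 to 2.5 and from day 2.5 to 3.5.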

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

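Released day 3.5 embryos, given as 8-cell, lay nearer to control day 3.5 than to control day 2.5 embryos; the tests between gaps and of elapsed time were chosen only after the result was seen. Within replicate numbers the distance to control day 3.5 was at most 0.728 of that to control day 2.5, so the pattern held within each number. A shift between the numbers that all groups share could not have caused it, since each group held both numbers. The change from control day 2.5 correlated at r = 0.111 with the difference between replicate numbers, which decides nothing on RNA integrity, because the GAPDH gap was larger on replicate 2 in only 3 of 6 groups. In the other groups the GAPDH 5′ signal was low (4.32 to 6.36), so that its gap there is uncertain. Each released array was nearer to the control day 3.5 array of the other number than to the control day 2.5 array of its own, by a ratio of at most 0.763. Its actin and GAPDH gaps were nevertheless closer to the latter, so these gaps alone did not set the nearness. The GAPDH gap of released replicate 2 was 0.724 from the former and 0.578 from the latter, a small contrast. The GAPDH 5′ signal of the control day 2.5 arrays, at 5.38 and 4.32, also lay near a level of 5. A part played by RNA integrity is therefore not excluded. Released embryos had covered 0.699 of the distance from control day 2.5 to control day 3.5, but this restates the pattern, so that elapsed time and a cell number other than that given stay open.

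Of 11 genes of the 2-cell list, 4 were higher in released than in control day 3.5 embryos (list adjusted p = 0.0721 with an estimated correlation). All tests of this pattern were chosen only after the result was seen. A mixture with embryos of the control day 1.5 profile would need a median of 75.2% of them to account for the 4 genes called, but maternal oocyte genes gave a median of 0.308%, which excludes it. A slower loss of transcripts during the arrest would not raise them afterwards, but the 4 genes were a median of 3.43 log2 units higher in released than in arrested embryos. Tcstv1 (3.25 ± 0.72), Tcstv3 (3.62 ± 0.90) and Usp17la (3.79 ± 1.02) argue against a slower loss for themselves. The arrested arrays were far apart, at 4.72 and 7.41 for Usp17la, and the genes were chosen on the same released arrays. For Zfp352 (1.07 ± 0.79) a slower loss stays open. A set of 6 that added Tdpoz1 (1.90) and Sp110 (-0.76), tried once these values were known, gave 2.57. The genes rising to blastocyst had a median of -0.12 log2 units, above a limit of -0.30, which is 0.5 of the value that stalled embryos would need at the lowest share (-0.60), but 2-cell levels were assumed for such embryos, so they stay open; 2 other limits, from the spread of the genes, were tried once the value was known and dropped. The genes rising to blastocyst were chosen in part on the control day 3.5 arrays, against which their median was also taken. That choice can lower the median. Usp17la, Tcstv1 and Tcstv3 belong to families of similar copies, and cross-hybridization within them was not tested.

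ERK targets did not fall together under U0126, and the tests of this pattern were likewise chosen only after the result was seen. Levels kept from the 2-cell stage stay open, as 9 of 18 targets lay between control day 1.5 and control day 2.5, 8 above both and 1 below both, while 52.4% of all genes lay between. Fos lay 1.66 log2 units above the higher of these controls, but both lay under a level of 5, so that the same explanation stays open for it. A stress or handling response could not be told apart, because the median of the stress list was -0.0736 while 3 of its 23 genes rose. ERK activity itself was not analysed here.

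The last step differed between released and control embryos for 232 genes, but it started from unlike positions, 0.932 in released and 0.774 in control embryos. Before the released step, Nanog (10.63) and Tex19.2 (8.53) already lay near their control day 3.5 levels (11.09 and 8.59). By the differences in log2 units, Elf5 stood at 5.53, Limch1 at 4.39, Fam189a2 at 4.20, Gulp1 at 4.16 and Sox17 at 3.76 towards released embryos. Hmox1 at -4.90, Lama3 at -4.80, Tex19.2 at -4.50, Pramel18 at -4.48 and Nanog at -3.27 lay on the other side. Dusp6 differed by 3.09 and Myc by 1.79. On both arrays of a group, Elf5, Gulp1, Sox17, Hmox1, Lama3 and Pramel18 lay under a level of 5 in control day 2.5 and Fam189a2 and Dusp6 in control day 3.5 embryos, among others, so the size of these differences rests on signal near background. Leaving out 1 array at a time, Elf5, Hmox1 and Lama3 passed each time. Tex19.2 (adjusted p = 0.0526) and Nanog (adjusted p = 0.0518) did not pass without released day 4.5 replicate 2. Fam189a2 did not pass without control day 2.5 replicate 2 (adjusted p = 0.0563), control day 3.5 replicate 2 (adjusted p = 0.0617) or released day 4.5 replicate 2 (adjusted p = 0.0655). Dusp6 did not without control day 3.5 replicate 2 (adjusted p = 0.0589), released day 3.5 replicate 2 (adjusted p = 0.0510) or released day 4.5 replicate 2 (adjusted p = 0.0681). Myc lost its call without any 1 of control day 2.5 replicate 1, control day 2.5 replicate 2, control day 3.5 replicate 1, control day 3.5 replicate 2, released day 3.5 replicate 1, released day 3.5 replicate 2, released day 4.5 replicate 1 and released day 4.5 replicate 2 (adjusted p = 0.104, 0.133, 0.111, 0.122, 0.0927, 0.135, 0.140 and 0.113, in this order). Pramel18 lost it without any of these but released day 3.5 replicate 1 (adjusted p = 0.0921, 0.128, 0.0663, 0.140, 0.0969, 0.105 and 0.144). Sox17 lost it without any of these but released day 3.5 replicate 2 (adjusted p = 0.0660, 0.0971, 0.0662, 0.0937, 0.0877, 0.0502 and 0.120). Limch1 lost it without any of these but control day 3.5 replicate 2 and released day 4.5 replicate 1 (adjusted p = 0.0588, 0.0738, 0.0597, 0.0722, 0.0605 and 0.0985). Gulp1 lost it without any of these but control day 3.5 replicate 1, released day 3.5 replicate 2 and released day 4.5 replicate 1 (adjusted p = 0.0650, 0.0679, 0.0617, 0.0740 and 0.0918). Among probe sets without a single gene name, 92 were higher under U0126 than in control day 2.5 embryos.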

How the results depend on the processing

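The replicate number as a block gave more changed genes, 2018 for released day 3.5 against control day 2.5, 1017 for released day 4.5 against control day 3.5, 2165 for the step between the released groups and 615 for the interaction. The groups shared part of their difference between replicate numbers (r from 0.125 to 0.417 across genes), and a block takes that part out of the spread. Where the shared part came from was not tested. Leaving out 1 array at a time, with the array left alone assumed to vary like the other groups, lowers the precision by construction. The loss was not only of that kind, since the counts also depended on which array of a group was left out, as for control day 3.5. The counts then ranged from 677 to 1565 for control day 3.5 against day 2.5, 409 to 1183 for U0126 against control day 2.5 and 1630 to 2372 for released day 3.5 against U0126 embryos. They ranged from 268 to 577 for released day 3.5 against control day 2.5, 1 to 30 against control day 3.5, 84 to 541 for released day 4.5 against control day 3.5, 321 to 759 against released day 3.5, and 30 to 115 for the interaction. The positions stayed within 0.734 to 0.797 for control day 2.5, 0.579 to 0.640 for U0126, 0.896 to 0.940 for released day 3.5 and 1.0 to 1.02 for released day 4.5 embryos.

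Fitting only the arrays compared left 2 residual degrees of freedom and gave 0 genes for U0126 against control day 2.5, 1381 for released day 3.5 against U0126, 13 for released against control day 3.5 and 313 for released day 4.5 against control day 3.5. For released against control day 3.5, 2 genes passed without a filter and 15 with a pseudocount of 16, and the cause was not tested.

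The genes rising from 2 to 8 cells passed as a set in released day 4.5 embryos after median centring (median -0.158), without a filter (-0.119), with a pseudocount of 16 (-0.122), with the block (-0.131) and with a mean-variance trend (-0.125). Leaving out arrays gave medians from -0.139 to -0.0834 for this set and from 0.0196 to 0.0531 for the falling set, which also passed at a minimum level of 7 (0.0329). Each alternative also chose the set anew, and with the block on the sets as first chosen p was 0.0761 for the rising and 0.0766 for the falling genes by camera. The position at that level was 0.936 for released day 3.5 and 1.02 for released day 4.5 embryos, the latter also with the mean of all probe sets.

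Another probe set of the same gene gave the opposite sign for Fgfr2 (-0.0725), Sos1 (-0.67), Dab2 (-0.0136), Heatr1 (-0.31) and Laptm5 (0.41) from control day 1.5 to 2.5, Ocln (0.0495) for U0126 against control day 2.5, Gata6 (-0.42) for U0126 against control day 1.5, Cnpy2 (-0.0478) for released day 3.5 against control day 2.5 and Ndufs4 (-0.46) for released day 4.5 against control day 3.5. Other probe sets also took away 73 calls of named genes and added 2. The estimated correlation removed 56 of 58 list calls. Among 180 list tests the block took away 4 calls and added 1, median centring took away 1 and added 1, and the lack of a filter took away 1 and added 10. Among named genes the block added 14 calls, median centring took away 17 and added 3, the pseudocount took away 15 and added 10, and the mean of all probe sets took away 20 and added 5. Quantile normalization, the minimum level of 7, the trend and the 2-fold minimum moved no count of changed genes by over 1.5 times, and among the lists and named genes the block changed no other call. Signal near background limits what can be seen, since from 66.5% to 68.7% of the probe sets on an array lay under a log2 level of 5.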

Other observations

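Genes that differed under U0126 were followed into released embryos and compared with normal development. The test of persistence was written before the result was seen, and that of a delay was chosen only after. Genes higher under U0126 differed from genes lower by a median of only 0.0422 log2 units between released day 4.5 and control day 3.5 embryos. This argues against persistence of the difference over these genes as a whole. Of 915 genes higher under U0126, 38 were higher and 12 lower in that comparison. Of 469 genes lower under U0126, 22 were higher and 19 lower. Persistence in single genes is not excluded, and the released embryos were also older than these controls. Across genes the U0126 effect correlated at r = -0.462 with the change from control day 1.5 to control day 3.5, which shares no array with it. This is consistent with a delay along that path, as are 351 genes higher than control day 2.5 and lower than control day 1.5 (202 for independent lists) and 168 the other way (132), but the genes are not independent and 265 lay above both control groups (257).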
